A study of Mus musculus with 9 samples.

How the data were processed

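Ribosome footprints were sequenced from mouse preadipocytes of inguinal white adipose tissue, a subcutaneous fat depot, at 3 stages of beige adipocyte differentiation in culture. Per the labels, cells were either not induced (day 0) or differentiated for 4 or 8 days, with 3 libraries per group and 9 in all. Induction medium held dexamethasone, a phosphodiesterase inhibitor, indomethacin, insulin, triiodothyronine and rosiglitazone. After 2 days it was replaced by medium without dexamethasone, the phosphodiesterase inhibitor and indomethacin. Lysates held cycloheximide, were digested with RNase I and were depleted of ribosomal RNA before the libraries were made.

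The deposited values are counts, raw and not normalised, with 1 column per library and 1 Ensembl gene per line. Per the submitters' processing notes, adapters were trimmed with cutadapt, reads were aligned to GRCm39 with HISAT2 and genes were counted with featureCounts. Tool versions, the strand setting, the counted feature and the handling of reads that map to several places are not given in the sources used here. The values are whole numbers that sum to 30823028 to 38994892 counts per library. The table holds 55359 genes, of which 28536 had 0 counts in all libraries. Gene classes were taken from a reference table of an earlier mouse assembly, matched by symbol or synonym, which covered 14378 of the tested genes, and no positions were used. Matched RNA levels were not analysed here, so footprint counts combine the amount of an mRNA with the ribosomes on it.

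Groups were taken from the labels. The origin of the replicates (animals, cultures or preparations) is not stated, so p-values measure only the spread between these libraries. Genes were filtered with filterByExpr (minimum count 10), which left 14714 genes holding at least 99.95% of the counts of each library. Counts were scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term and all 9 libraries sharing 1 estimate of spread. Day 4 was compared with day 0, day 8 with day 0 and day 8 with day 4, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Normalised read counts (CPM) use TMM-scaled library sizes and are given as mean ± SD with n = 3. Fold changes are fitted log2 values with the standard error (SE) derived from the quasi-likelihood F statistic, unless said otherwise. Where a group had 0 counts in all its libraries, the fold is a lower bound against 3 counts per library. Where a group had 1 to 3 counts in all, the ratio of mean CPM is given with its 95% exact Poisson interval. Such intervals and floors cover counting error only.

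A total of 40 gene lists were fixed before the data were examined, and 37 had at least 3 tested members. They cover fat cell identity, thermogenesis, precursors, lipid and energy metabolism, translation, amino acids, matrix, cytoskeleton, cell cycle, protein folding and breakdown, hormone and immune responses, and markers of other cell types. Each was compared with all other tested genes by camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and adjustment over the 37 lists. The same test with an estimated correlation was run beside it, as was fry, which tests whether the genes of a list move on balance one way. Members of a list are counted as higher or lower when called over all tested genes, and again when adjusted over the list alone.

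The named genes follow a rule that was fixed before the data were examined. It takes 10 marker genes throughout. It adds, per comparison, the 6 largest rises and the 6 largest falls among called genes with a mean of at least 100 counts per library in the higher group and no overlap between the libraries of both groups. Predicted genes and pseudogenes were left out of these. From each list it takes up to 3 members with the smallest adjusted p, and where no member was called the 2 with the highest counts. Not all genes that the rule takes are reported here.

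Shares of counts per library were compared over the 3 groups by an exact permutation test of the between-group sum of squares over all 1680 arrangements, with a smallest possible p of 0.00357. The overlap of both comparisons against day 0 was set beside the number for independent calls and beside 20 simulations of unchanged groups against the same day 0 libraries. Other groupings of the libraries were drawn for each count of genes and lists. Alternatives fixed beforehand changed the scaling, the low-count filter, the test (DESeq2 1.42.0, limma-voom, a 1.5-fold threshold), the libraries in the fit, a block for replicate number, the genes counted and each library in turn. A fit without day 4 replicate 2 and day 8 replicate 3 together was chosen after seeing the data. The tests were also tried on simulated data with 200 changed genes per comparison. Genes changed 4-fold were recovered in 93% to 94% and genes changed 2-fold in 67% to 73%, in 1 simulation per comparison. The share of false calls was 4.52% for day 4 against day 0, 4.64% for day 8 against day 4 and 9.36% for day 8 against day 0 (19 of 203 calls), the last above the 0.05 aimed at. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.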

Results

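Ribosome footprints, the mRNA fragments that ribosomes protect from RNase, were counted per gene in cultured inguinal preadipocytes before induction and after 4 or 8 days of beige adipocyte differentiation. Beige adipocytes are fat cells that can burn lipid for heat. The series was set up to measure translation activity over this differentiation. Replicates 1, 2 and 3 had 31050850, 30823028 and 35836063 counts at day 0. They had 36768535, 38035996 and 38994892 counts at day 4, and 34979779, 35881351 and 34870272 counts at day 8. The first principal component of log2 CPM held 75.9% of the variance and placed day 0 apart from both later days, and the second held 13.7% and parted day 4 from day 8. Within day 4, replicate 2 lay nearer to day 0, at 12.8 on the first component against 64.8 and 65.4 for the other libraries of that day. In that library Pparg stood at 209.5 CPM against 359.9 and 353.8, Pdgfra at 692.4 CPM against 314.2 and 386.1, and Ly6a at 534.4 CPM against 221.2 and 251.6. Ly6a was higher at day 4 than at day 0 (log2 fold change 0.86, and 0.36 without day 4 replicate 2). Its level in that library thus does not lie toward day 0. Day 8 replicate 3 lay at 62.1 against 85.5 and 85.8, with Ucp1 at 129.5 CPM against 292.6 and 327.6 and Cidea at 326.4 CPM against 732.6 and 730.2. The totals of changed genes per comparison, the shared calls and some list counts are therefore also given without day 4 replicate 2 and day 8 replicate 3. That choice was made after seeing the data.

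**Figure D1:**
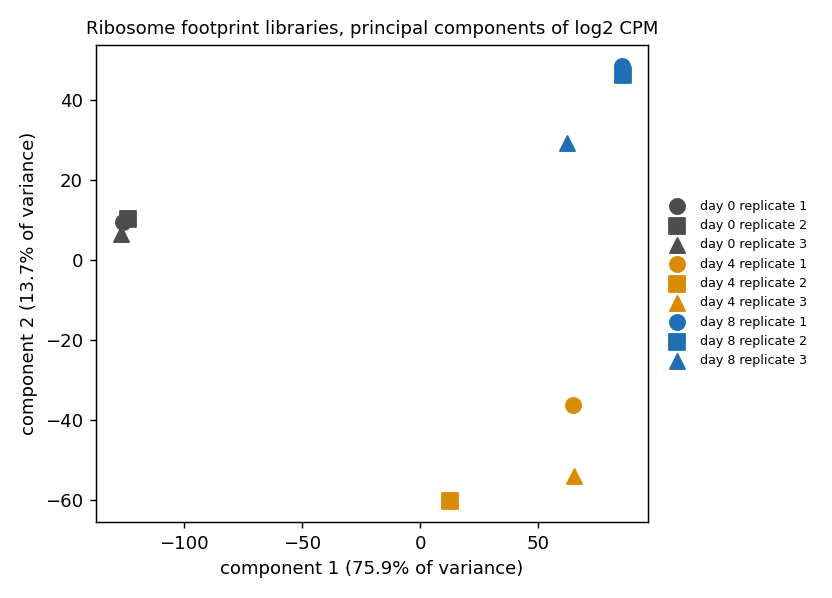
Each point is 1 library on the first (horizontal, 75.9% of the variance) and second (vertical, 13.7%) principal component of log2 CPM, with colour for the day and shape for the replicate number. Day 4 replicate 2 lies at 12.8 on the first component, between day 0 and the other day 4 libraries at 64.8 and 65.4.

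The comparison of day 4 with day 0 asked which footprint levels changed as precursors became fat cells. The fat cell regulators and products rose by large factors by day 4. Adipoq (ENSMUSG00000022878), which encodes the hormone adiponectin, rose 292-fold, from 10.8 ± 0.694 to 3144 ± 436 CPM (SD, n = 3; log2 fold change 8.19 ± 0.21 SE). Fabp4 (ENSMUSG00000062515), a fatty acid carrier, rose 184-fold to 34390 ± 8040 CPM (7.52 ± 0.33). The fat cell transcription factors Pparg (ENSMUSG00000000440) and Cebpa (ENSMUSG00000034957) rose 16.2-fold and 20.6-fold (4.02 ± 0.29 and 4.37 ± 0.23). Thermogenic genes were higher too but still low in level: Ucp1 (ENSMUSG00000031710), the proton carrier of heat production, rose 14.6-fold to 9.19 ± 6.80 CPM (3.87 ± 0.66). Cidea (ENSMUSG00000024526), a lipid droplet protein of brown and beige fat, rose 5.53-fold (2.47 ± 0.57), and Ppargc1a (ENSMUSG00000029167), a coactivator of mitochondrial genes, rose 58.5-fold (5.87 ± 0.34). Without day 4 replicate 1 the log2 fold change was 3.12 for Ucp1 and 1.63 for Cidea.

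Precursor genes moved less evenly. The precursor receptor Pdgfra (ENSMUSG00000029231) had a log2 fold change of -0.53 ± 0.29 (adjusted p = 0.146). It passed the test at -0.93 without day 4 replicate 2 (adjusted p = 0.00329) and was -0.31 without replicate 1. Dlk1 (ENSMUSG00000040856) and Ly6a (ENSMUSG00000075602), surface proteins of precursors, rose by 0.77 ± 0.28 and 0.86 ± 0.31 (adjusted p = 0.0366 and 0.0338). Neither was called without day 4 replicate 2 (0.54 and 0.36, adjusted p = 0.0978 and 0.0795) or without day 0 replicate 2 (0.52 and 0.84, adjusted p = 0.104 and 0.0898), and Ly6a was not called without day 0 replicate 3 (0.73, adjusted p = 0.116). Over all alternatives the adjusted p ran from 7.94e-05 to 0.598 for Pdgfra, from 0.0109 to 0.247 for Dlk1 and from 0.00526 to 0.185 for Ly6a.

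Some large rises by day 4 were in genes with few or no counts at day 0. Alkal2, which encodes a ligand of the receptor ALK, and Trim67, a ubiquitin ligase, had 0 counts there and were at least 85.2-fold and at least 48.1-fold higher. Gys2, a glycogen synthase, had 3 counts at day 0, all in replicate 2, and a ratio of 831 (297 to 4210). The inositol trisphosphate kinase gene Itpka and Wfdc21 had 1 count each and ratios of 845 (159 to 34900) and 837 (140 to 30800). Sptlc3, a subunit of the enzyme that starts sphingolipid synthesis, rose 486-fold (8.93 ± 0.44). Large falls were seen in Mmp13 (63.3-fold, -5.98 ± 0.60) and Mmp12 (45.9-fold, -5.52 ± 1.13), which encode matrix-cutting proteases, in Fbxl22 (60.3-fold, -5.91 ± 0.62), in Crabp2, a retinoic acid carrier (54.4-fold, -5.77 ± 0.67), in Lrrc15 (50.9-fold, -5.67 ± 0.72) and in the homeobox gene Gbx2 (49.9-fold, -5.64 ± 0.68). Without day 0 replicate 3 the log2 fold change of Sptlc3 was 10.4, and without day 4 replicate 1 those of Fbxl22 and Lrrc15 were -7.41 and -6.33. Mmp12 was not called by limma-voom (adjusted p = 0.0553, with a range over its alternatives of 6.42e-07 to 0.0553).

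All 21 tested genes of the adipocyte identity list rose, with a median log2 fold change of 7.50. Among them the fatty acid receptor Cd36 rose 264-fold (8.05 ± 0.28) and the acyl-CoA synthetase Acsl1 181-fold (7.50 ± 0.25). The list had a camera adjusted p = 1.52e-15, and an adjusted p = 0.322 with an estimated correlation. Of 28 thermogenic and beige genes 17 rose and 3 fell, with Elovl3, a fatty acid elongase, 175-fold higher (7.46 ± 0.24) and Ppargc1b 58.5-fold higher (adjusted p = 0.000388 for the list, and adjusted p = 0.335 with an estimated correlation). Lipolysis rose in 15 of 16 genes, among them the triglyceride lipase Pnpla2 (85-fold, 6.41 ± 0.25) and the droplet coat gene Plin1 (225-fold, 7.81 ± 0.28). Triglyceride synthesis and lipid droplet genes rose in 17 of 19 and fell in 1, with the droplet protein Cidec 360-fold higher (8.49 ± 0.28). Fatty acid synthesis rose in 14 of 18 and fell in 1, with Fasn and Acaca, its central enzymes, 27.1-fold and 19.8-fold higher. Adjusted p was 4.07e-11, 2.1e-08 and 1.87e-05 for these 3 lists, and adjusted p = 0.322 with an estimated correlation for each. The same counts came out adjusted over the list alone. Fatty acid synthesis had 3 lower genes without day 4 replicate 2 and day 8 replicate 3. The identity, lipolysis and droplet lists share members, among them Pnpla2, Plin1 and Cidec, so their results are not independent.

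Most genes of the mitochondrial and oxidative lists rose. All 58 nuclear genes of the respiratory chain rose, with a median of 2.20 (Uqcrfs1 13.4-fold, Ndufb3 6.38-fold), as did all 25 citric acid cycle genes, with a median of 2.80 (Idh3a 18.3-fold, pyruvate carboxylase Pcx 76.4-fold). Adjusted p was 3.27e-18 and 5.15e-13, and adjusted p = 0.322 with an estimated correlation for both. Fatty acid oxidation rose in 23 of 25 genes and fell in 1 (Ehhadh 41.3-fold higher), the mitochondrial ribosome rose in 74 of 77 and fell in 1 (Mrps22 5.05-fold higher, Mrps35 5.70-fold), and nuclear ATP synthase genes rose in 14 of 15 (Atp5c1 3.91-fold). Adjusted p was 3.41e-12, 2.74e-17 and 5.24e-07, and adjusted p = 0.322 with an estimated correlation for each. Of the 13 protein genes of mitochondrial DNA 11 rose, by a smaller median of 0.86 (mt-Nd2 3.07-fold, mt-Nd1 2.00-fold; adjusted p = 0.00105, and adjusted p = 0.322 with an estimated correlation). With p adjusted over the list alone 12 of these 13 rose, and the other counts were the same.

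Most genes of branched-chain amino acid breakdown, sugar use, the proteasome and the list of genes that dexamethasone is known to induce rose as well. Dexamethasone was in the medium only for the first 2 days, and what raised that list was not tested. Branched-chain amino acid breakdown rose in 24 of 25 genes and fell in 1, with the transaminase Bcat2 16.5-fold and Dbt, a subunit of the next enzyme, 8.74-fold higher. All 8 pentose phosphate genes rose, with G6pdx, the enzyme at its entry, 7.94-fold and Taldo1 7.77-fold higher. The proteasome rose in 29 of 31 genes by a median of 0.62 (Psma1 7.70-fold, Psma6 2.08-fold), and genes that dexamethasone is known to induce rose in 12 of 13 (Zbtb16 259-fold, Fkbp5 12.1-fold). Adjusted p was 6.22e-10, 4.5e-05, 1.57e-07 and 1.47e-06 for these lists, and adjusted p = 0.322 with an estimated correlation for each. Glycolysis rose in 15 of 20 genes (Ldhb 13.1-fold, the regulatory enzyme gene Pfkfb3 18-fold; adjusted p = 0.00283, and adjusted p = 0.605 with an estimated correlation). The glutamate, aspartate and urea-related list was not called (10 of 20 higher and 4 lower, 12 and 7 without day 4 replicate 2 and day 8 replicate 3, adjusted p = 0.0867). It was called without the low-count filter (adjusted p = 0.0161, range over its alternatives 0.0161 to 0.112). Within it the alanine transaminase Gpt rose 74.8-fold, the aspartoacylase Aspa 46.6-fold and the glutamine synthetase Glul 33.5-fold. Amino acid transporters went both ways, 8 higher and 11 lower of 23, with a median of -0.39, a mean of 0.50 and a test direction of down (adjusted p = 0.736; by fry up, adjusted p = 0.0034). In that list Slc36a2 rose 153-fold and the glutamine carrier Slc1a5 12.9-fold, and Slc1a4 fell by 1.18 on the log2 scale. When adjusted over the list alone 1 glycolysis gene fell, and the other counts were the same.

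Most contractile, cell cycle and inflammatory genes of the lists fell. Of 21 cytoskeleton and smooth muscle genes 20 fell, by a median of -2.70, with the myosin light chain Myl9 23.5-fold and tropomyosin Tpm1 10-fold lower (adjusted p = 1.45e-08, and adjusted p = 0.322 with an estimated correlation). Cell cycle genes fell in 24 of 34 and rose in 2, with the replication helicase gene Mcm2 1.88-fold and E2f1 1.89-fold lower and Ccne1 1.90-fold higher (adjusted p = 0.000146, and adjusted p = 0.575 with an estimated correlation). Interferon and inflammatory genes fell in 15 of 20 and rose in 3. Ptgs2, a prostaglandin synthase, was 42.7-fold and Il6 27.9-fold lower (log2 -5.42 ± 0.38 and -4.80 ± 0.62, -5.58 for Il6 without day 4 replicate 2), and Nfkbia, an inhibitor of NF-kB, was 3.27-fold higher (adjusted p = 0.00178, and adjusted p = 0.546 with an estimated correlation). The precursor list fell in 15 of 25 and rose in 4, with Vcam1 6.50-fold and Pdgfrb 4.63-fold lower and Zfp423, a zinc finger protein of fat cell commitment, 5.03-fold higher (adjusted p = 0.0165, and adjusted p = 0.605 with an estimated correlation). Collagen and matrix genes split, with 11 of 42 higher and 17 lower (adjusted p = 0.168). Col5a3 rose 13.8-fold, and the basement membrane genes Col15a1 and Col18a1 rose 5.97-fold and 4.79-fold. Without day 4 replicate 2 and day 8 replicate 3 the matrix list was lower as a whole, with 11 higher and 26 lower (adjusted p = 0.019, with a range over its alternatives of 0.019 to 0.287). Counts adjusted over the list alone had 19 matrix genes lower, and the other counts in this paragraph were the same.

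In all, edgeR called 8563 of 14714 genes between day 4 and day 0, 4387 higher and 4176 lower, and 10001 without day 4 replicate 2 and day 8 replicate 3. Of the 37 lists 20 were called, 16 up and 4 down, 22 without those libraries and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05 and the lowest adjusted p was 0.322. By fry, 28 lists moved on balance one way. Atp5c1 and Ldhb have 1 named pseudogene each, so their counts are less certain. Scaling by library totals or the upper quartile moved the median log2 change of all genes by -0.154 and -0.127 in this comparison, and made more of the called genes lower than higher (41.9% and 43.2% higher, against 51.2%). No list called here changed direction under them.

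**Figure D2:**
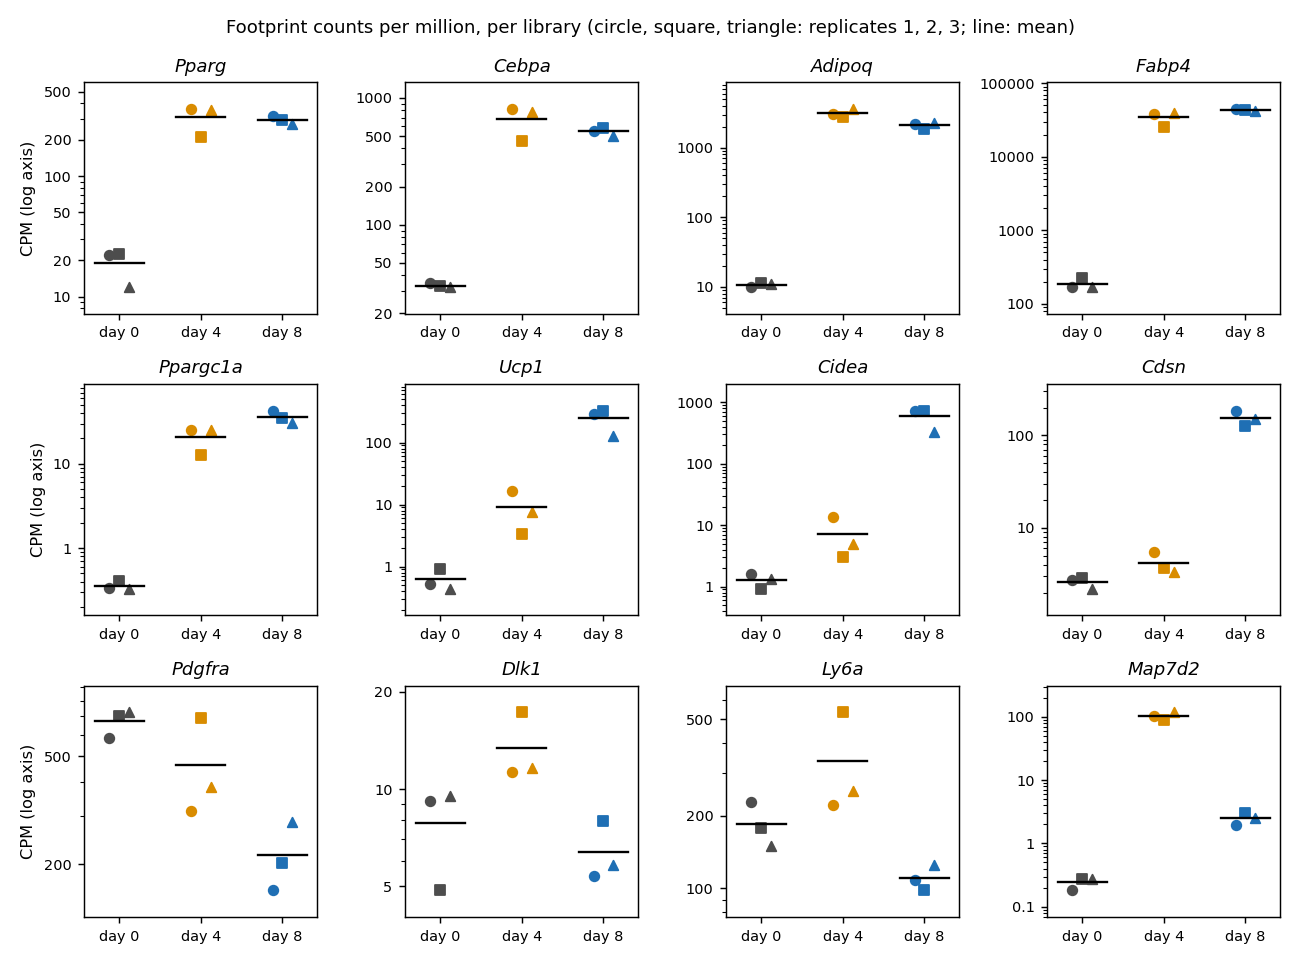
Normalised footprint counts (CPM, log axis) of 12 genes in each library at day 0, day 4 and day 8, with symbols for replicates 1 to 3 and a line at the mean of 3. Ucp1 means were 0.629, 9.19 and 249.9 CPM, and Fabp4 means were 187.2, 34390 and 43290 CPM.

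Day 8 was compared with day 0 to describe the later stage against the precursors. Thermogenic and general fat cell markers were both far above day 0. Ucp1 rose 398-fold to 249.9 ± 106 CPM (SD, n = 3; log2 fold change 8.64 ± 0.73 SE), Cidea 461-fold to 596.4 ± 234 CPM (8.85 ± 0.69) and Ppargc1a 100-fold (6.65 ± 0.34). Adipoq rose 195-fold (7.61 ± 0.20), Fabp4 231-fold (7.85 ± 0.33), Pparg 15.5-fold (3.96 ± 0.29) and Cebpa 16.4-fold (4.04 ± 0.22). Pdgfra fell 3.11-fold (-1.64 ± 0.30), while Dlk1 had a log2 fold change of -0.30 ± 0.28 (adjusted p = 0.36), and -0.14 to -0.55 when each library was left out in turn. Ly6a stood at -0.74 ± 0.31 (adjusted p = 0.0532) and passed the test without day 4 replicate 1 (-0.74, adjusted p = 0.0334) or replicate 2 (-0.74, adjusted p = 0.00123), with a range over its alternatives of 0.000344 to 0.259.

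Among genes with few or no counts at day 0, Flacc1 and Trim67 had 0 counts there and were at least 45.7-fold and at least 45.5-fold higher. Otop1, a proton channel of brown fat, rose 752-fold (9.55 ± 0.53). Gipr, the receptor of the gut hormone GIP, and Gys2 had 3 counts each at day 0, those of Gys2 all in replicate 2, and ratios of 749 (265 to 3760) and 554 (198 to 2810), and Itpka had 1 count and a ratio of 682 (128 to 28200). The log2 fold change of Gipr was 9.43, and 10.3 without day 0 replicate 1. Large falls were also seen: Crabp2 fell 78.3-fold (-6.29 ± 0.70), C1qtnf3 72.1-fold (-6.17 ± 0.82), Matn4 62.7-fold (-5.97 ± 0.78), Scg2 56.5-fold (-5.82 ± 0.72), Gxylt2, a xylosyltransferase, 55-fold (-5.78 ± 0.50) and Ccn3 54.6-fold (-5.77 ± 0.78), from 1873 ± 83.9 to 34.3 ± 37.7 CPM. Without day 8 replicate 3 these falls were deeper, with log2 fold changes of -8.49 for Crabp2, -8.17 for C1qtnf3, -7.21 for Ccn3, -6.96 for Scg2 and -6.45 for Gxylt2, and Scg2 stood at -5.23 without day 0 replicate 3.

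Fat cell and thermogenic lists stood high. All 21 adipocyte identity genes rose, with a median of 7.60, and 21 of 28 thermogenic and beige genes rose while 3 fell, 5 without day 4 replicate 2 and day 8 replicate 3 (Elovl3 237-fold, the nuclear receptor Ppara 189-fold). All 16 lipolysis genes rose (the glycerol channel Aqp7 200-fold, the receptor Hcar2 143-fold), 15 of 18 fatty acid synthesis genes rose (Acacb 130-fold), and 16 of 19 triglyceride and droplet genes rose while 1 fell. Adjusted p was 5.5e-13, 1.1e-05, 3.83e-10, 6.13e-05 and 1.41e-07, and adjusted p = 0.364 with an estimated correlation for each. Respiratory chain genes of the nucleus rose in 58 of 58 (Ndufa10 9.03-fold), citric acid cycle genes in 25 of 25 (Idh3a 23.2-fold), mitochondrial ribosome genes in 74 of 77 (Mrps30 4.27-fold), fatty acid oxidation genes in 24 of 25 with 1 lower (Acaa2 20.2-fold) and mitochondrially encoded protein genes in 11 of 13 (mt-Co1 2.85-fold). Adjusted p was 2.61e-18, 6.39e-12, 8.4e-17, 2.02e-11 and 0.000805, and adjusted p = 0.364 with an estimated correlation for each. Branched-chain breakdown rose in 24 of 25 genes with 1 lower, ATP synthase in 14 of 15, pentose phosphate genes in 8 of 8 and dexamethasone-induced genes in 11 of 13 with 1 lower (Angptl4 13.3-fold, Klf9 3.81-fold). Adjusted p was 6.1e-09, 3.26e-06, 0.000486 and 0.00121, and adjusted p = 0.364 with an estimated correlation for each. Glycolysis rose in 19 of 20 genes (Pfkp 7.16-fold, the lactate carrier Slc16a1 6.89-fold) and the proteasome in 26 of 31 with 1 lower (Psmb7 2.99-fold), with adjusted p = 5.19e-06 and 4.64e-05, and adjusted p = 0.44 with an estimated correlation for both. Adjusted over the list alone the counts in this paragraph were the same, except that 1 fatty acid synthesis gene and 1 mitochondrial ribosome gene fell.

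Most precursor, matrix, contractile and cell cycle genes of the lists fell by day 8. Precursor genes fell in 20 of 25 and rose in 1 (Vcam1 8.44-fold, the transcription factor Sox9 7.25-fold lower; adjusted p = 6.13e-05, and adjusted p = 0.428 with an estimated correlation). Matrix genes fell in 31 of 42 and rose in 6. Thbs2, a matrix glycoprotein, fell 10.6-fold to 884.2 ± 259 CPM, and Col15a1 rose 8.28-fold (adjusted p = 9.44e-05, and adjusted p = 0.552 with an estimated correlation). Cytoskeleton genes fell in 20 of 21 (Cald1 7.11-fold, Flna 6.61-fold; adjusted p = 7.23e-07, and adjusted p = 0.412 with an estimated correlation). Cell cycle genes fell in 32 of 34 and rose in 1 (Mcm2 3.82-fold, Mcm6 3.83-fold, the spindle checkpoint gene Bub1b 3.99-fold lower; adjusted p = 5.98e-09, and adjusted p = 0.364 with an estimated correlation). Cytosolic ribosomal protein genes fell in 42 of 81 and rose in 4, by a median of -0.52 (Rpl6 2.58-fold and Rpl21 3.48-fold lower, Rpl9 4.70-fold higher; adjusted p = 0.000622, and adjusted p = 0.573 with an estimated correlation). Footprint counts of Rpl21 and Rpl9 are uncertain, since 15 and 9 pseudogenes of their names are in the reference. How reads that map to several places were counted is not given, so the levels of ribosomal protein genes are uncertain. Macrophage markers fell in 7 of 14, with the complement genes C1qa 5.98-fold and C1qb 6.13-fold and Cd14 3.49-fold lower (adjusted p = 0.0394, and adjusted p = 0.591 with an estimated correlation). That call was lost without day 0 replicate 2 (adjusted p = 0.0623), day 0 replicate 3 (0.0868), day 4 replicate 2 (0.0628) or day 8 replicate 1 (0.0767), with the upper quartile (0.0583) and among genes of mean CPM of at least 10 (0.336), in a range of 0.00599 to 0.336. Adjusted over the list alone 21 precursor genes and 6 macrophage genes fell, and the other counts were the same.

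On simulated data the comparison of day 8 with day 0 had 9.36% false calls, with 200 changed genes and 30 shifted list members among 13839 tested. That share cannot be carried over to the real data, where far more genes were called. EdgeR called 9961 genes between day 8 and day 0, 5033 higher and 4928 lower, and 10638 without day 4 replicate 2 and day 8 replicate 3. Of the 37 lists 22 were called, 16 up and 6 down, 22 without those libraries and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05 and the lowest adjusted p was 0.364. By fry, 30 lists moved on balance one way, and of the 22 called lists macrophage markers did not pass it (adjusted p = 0.0734). Psmb7 has 2 named pseudogenes. The upper quartile moved the median gene by -0.107 and made 45.4% of the called genes higher, against 50.5%, and no list called here changed direction under any scaling.

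Day 8 was compared with day 4 to find what set the later stage apart. Ucp1 and Cidea rose further between these days. Cidea rose 83.3-fold, from 7.17 ± 5.61 to 596.4 ± 234 CPM (SD, n = 3; log2 fold change 6.38 ± 0.60 SE), and Ucp1 rose 27.2-fold, from 9.19 ± 6.80 to 249.9 ± 106 CPM (4.77 ± 0.58). Ppargc1a rose 1.71-fold (0.77 ± 0.24, adjusted p = 0.0327) and Adipoq fell 1.5-fold (-0.59 ± 0.15, adjusted p = 0.0168). Pparg (-0.07 ± 0.26, adjusted p = 0.865), Cebpa (-0.33 ± 0.20, adjusted p = 0.232) and Fabp4 (0.33 ± 0.24, adjusted p = 0.326) did not pass the test. The precursor genes Ly6a, Pdgfra and Dlk1 fell 3.04-fold, 2.15-fold and 2.1-fold (-1.60 ± 0.31, -1.11 ± 0.30 and -1.07 ± 0.28). Some of these calls were lost without 1 library, with folds in the same direction. Adipoq was not called without day 4 replicate 3 (-0.48, adjusted p = 0.0546) or day 8 replicate 2 (-0.51, 0.0711), Pdgfra without day 8 replicate 1 (-0.94, 0.0771) or 2 (-1.07, 0.0685), and Dlk1 without day 8 replicate 1 (-0.97, 0.0698). Ppargc1a was not called without day 0 replicate 1 (0.77, 0.0513) or 3 (0.77, 0.0502) or day 8 replicate 1 (0.63, 0.124) or 2 (0.79, 0.0777), while Cebpa was called without day 4 replicate 2 (-0.55, adjusted p = 0.00231). Without day 4 replicate 2 the log2 fold change was 0.51 for Ppargc1a, -0.70 for Pdgfra, 0.15 for Fabp4 and -0.28 for Pparg, and without day 4 replicate 1 it was 5.52 for Ucp1, 7.23 for Cidea, -0.18 for Cebpa and 0.06 for Pparg. Pparg was also above 0 without day 4 replicate 3 (0.04). Over their alternatives adjusted p ran from 0.000312 to 0.801 for Adipoq, 0.00048 to 0.147 for Pdgfra, 0.00198 to 0.148 for Dlk1, 0.00239 to 0.413 for Ppargc1a and 0.00151 to 1 for Cebpa.

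Beside Cidea, large rises were seen in Mmp12, which returned to 6.37 ± 5.24 CPM (80.9-fold, 6.34 ± 1.12), the nitric oxide synthase gene Nos2 (70.8-fold, 6.15 ± 0.48), the chloride channel gene Ano1 (63.9-fold, SE 0.83), Cdsn, which encodes corneodesmosin, a cell adhesion protein of the skin (37.1-fold, 5.21 ± 0.24), and the microRNA gene Mir182 (29.8-fold, 4.90 ± 1.12). Footprints at a microRNA gene are uncertain in origin, and limma-voom called neither Mir182 (adjusted p = 0.0568, range 0.000139 to 0.0568) nor Mmp12 (adjusted p = 0.0639, range 3.69e-08 to 0.0639). Large falls were seen in the chemokine Cxcl13 (62.6-fold, -5.97 ± 0.71), Map7d2, a microtubule-binding protein (41-fold, -5.36 ± 0.18, from 103.1 ± 14.3 to 2.51 ± 0.507 CPM), Vit (37.4-fold, -5.23 ± 0.56), the decoy interleukin receptor Il1r2 (34.2-fold, -5.10 ± 0.56), the precursor marker Pi16 (32.9-fold, -5.04 ± 0.81) and Clca3a1 (29.1-fold, -4.87 ± 0.62). Clca3a1 has a close paralog, so its count is uncertain. Single libraries moved several of these folds: the log2 fold change was 5.65 for Mmp12 and 4.09 for Mir182 without day 8 replicate 2, -4.11 for Pi16 and -3.88 for Clca3a1 without day 4 replicate 2, and -5.25 for Cxcl13 without day 4 replicate 3. Without day 8 replicate 3 it was -6.50 for Pi16 and -6.23 for Il1r2.

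Lists that rose from day 4 to day 8 covered heat production, respiration, sugar use and stress. Thermogenic and beige genes rose in 13 of 28 and fell in 1 (Otop1 8.76-fold, the pyruvate dehydrogenase kinase Pdk4 5.27-fold higher; adjusted p = 3.14e-05). Nuclear respiratory chain genes rose in 29 of 58, by a median of 0.53 (Cox8b 4.34-fold, Ndufa12 1.99-fold; adjusted p = 2.64e-08). Glycolysis rose in 7 of 20 genes (Pfkp 3.34-fold, Slc16a1 2.84-fold; adjusted p = 2.88e-05). Integrated stress response genes, which ATF4 and CHOP induce, rose in 15 of 28 and fell in 3. Among them the transcription factor Atf3 rose 10.2-fold, the stress hormone Gdf15 9.50-fold and Ppp1r15a, a phosphatase subunit that restores translation, 4.96-fold (adjusted p = 0.000938). Chaperones and unfolded protein response genes of the endoplasmic reticulum rose in 12 of 23 and fell in 1 (Sdf2l1 3.68-fold, Herpud1 3.21-fold, the stress sensor Ern1 2.56-fold; adjusted p = 3.78e-05). Interferon and inflammatory genes rose in 8 of 20 and fell in 2 (Ptgs2 7.26-fold higher, Nfkbia 2.34-fold lower; adjusted p = 0.00804). Each of these 6 lists had an adjusted p = 0.792 with an estimated correlation. The interferon call was lost with library totals (adjusted p = 0.0512) and among genes of mean CPM of at least 10 (0.0985), in a range of 2.04e-05 to 0.0985. Fatty acid oxidation (7 of 25 higher, 3 lower, Acaa1b 5.62-fold higher with an uncertain count because of its paralog), the citric acid cycle (2 of 25 higher, 1 of them Idh2 at 2.19-fold) and the mitochondrial ribosome (19 of 77 higher, 2 lower, Mrps16 1.69-fold higher) had adjusted p = 0.0322, 0.0248 and 0.00231, and adjusted p = 0.931 with an estimated correlation for each. Without day 4 replicate 2 none of these 3 was called (adjusted p = 0.317, 0.63 and 0.244, with lowest values over the alternatives of 0.00364, 0.00163 and 4.6e-05). Fatty acid oxidation was also not called without day 8 replicate 1 (0.1) or 2 (0.0749), nor the citric acid cycle without day 8 replicate 1 (0.0883). Some counts rose by over 1.5 times without day 4 replicate 2 and day 8 replicate 3, with 45 respiratory chain genes higher and 1 lower, 15 and 3 for interferon, 11 and 0 for glycolysis, 12 and 4 for fatty acid oxidation, 8 and 3 for the citric acid cycle (adjusted p = 0.0875) and 5 stress response and 5 mitochondrial ribosome genes lower. Adjusted over the list alone 16 thermogenic genes rose and 2 fell, 38 respiratory chain genes, 9 fatty acid oxidation genes and 10 interferon genes rose, and the other counts were the same.

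Lists that fell covered the cytosolic ribosome, matrix, cell cycle, precursors and dexamethasone targets. Ribosomal protein genes fell in 48 of 81 and rose in 0, by a median of -0.64 (Rpl27 3.26-fold, Rpl6 2.41-fold, Rps21 1.89-fold; adjusted p = 1.17e-09). With library totals 31 fell and 1 rose, and without day 4 replicate 2 and day 8 replicate 3 39 fell and 0 rose. Rpl27 has 3 named pseudogenes, so its count is uncertain. Translation factors fell in 15 of 47 and rose in 2, with the scaffold of cap-dependent initiation Eif4g1 1.87-fold and Eif5a 1.75-fold lower and the helicase gene Eif4a2 1.92-fold higher (adjusted p = 0.00807). Without day 4 replicate 2 and day 8 replicate 3 the translation factor list was not called (13 lower, 4 higher, adjusted p = 0.0828, range 0.000849 to 0.0828). Matrix genes fell in 27 of 42 and rose in 1, with the basement membrane collagens Col4a2 3.21-fold and Col4a1 2.78-fold and elastin (Eln) 6.4-fold lower (adjusted p = 8.73e-07). Cell cycle genes fell in 27 of 34 (Mcm5 3.46-fold, Mcm7 1.95-fold; adjusted p = 1.63e-09) and precursor genes in 13 of 25 (Pi16, Procr 3.89-fold; adjusted p = 0.00125). Genes that dexamethasone induces fell in 7 of 13, with Fkbp5 6.26-fold and Tsc22d3 3.61-fold lower (adjusted p = 0.0091). All of these 6 lists had an adjusted p = 0.792 with an estimated correlation. Macrophage markers fell in 4 of 14 (C1qa 6.08-fold; adjusted p = 0.0375, and adjusted p = 0.931 with an estimated correlation). That call was lost without day 4 replicate 2 (adjusted p = 0.0919), day 4 replicate 3 (0.0647) or day 8 replicate 1 (0.176) and among genes of mean CPM of at least 10 (0.507), in a range of 0.00396 to 0.507. Adjusted over the list alone 52 ribosomal protein genes, 19 translation factors, 28 matrix genes and 30 cell cycle genes fell, 3 translation factors and 1 cell cycle gene rose, and the other counts were the same.

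Among lists that were not called, some members fell from their day 4 level. Fasn and Acaca fell 2.17-fold and 2.07-fold, and their regulator Srebf1 fell 1.80-fold (fatty acid synthesis, 3 of 18 higher and 6 lower, median -0.01, which turned positive with library totals and the upper quartile; adjusted p = 0.73). Cyp51 and Dhcr7, enzymes of cholesterol synthesis, fell 5.11-fold and 3.79-fold (0 of 24 higher, 6 lower, median -0.05, positive with library totals; adjusted p = 0.375). Glud1 and Glul, which make and use glutamate, fell 3.28-fold and 2.56-fold (5 of 20 higher, 10 lower, adjusted p = 0.511), and the glutamine carrier Slc1a5 fell 2.77-fold (amino acid transporters, 2 of 23 higher and 9 lower, 4 and 8 without day 4 replicate 2 and day 8 replicate 3, adjusted p = 0.208). Cbs, an enzyme of sulfur amino acids, fell 7.28-fold and the folate enzyme gene Aldh1l1 3.04-fold (serine and one-carbon metabolism, 2 of 22 higher and 8 lower, adjusted p = 0.208). Adipocyte identity genes (1 of 21 higher and 5 lower, 3 and 10 without day 4 replicate 2 and day 8 replicate 3, median -0.09, positive with library totals) had adjusted p = 0.73, and were called lower without day 4 replicate 2 (adjusted p = 0.0248, range 0.0248 to 0.934). Adjusted over the list alone 4 fatty acid synthesis genes and 6 glutamate-related genes rose, 5 cholesterol genes and 9 serine and one-carbon genes fell, and the other counts were the same.

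EdgeR called 4676 genes between day 8 and day 4, 2159 higher and 2517 lower, and 5481 without day 4 replicate 2 and day 8 replicate 3. The count was 2706 without day 8 replicate 1 and 2760 without day 8 replicate 2. Of the 37 lists 16 were called, 9 up and 7 down, 14 without day 4 replicate 2 and day 8 replicate 3 and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05. By fry, 12 lists moved on balance one way, and 8 of the 16 called lists did not pass it: precursor (adjusted p = 0.0666), glycolysis (0.0533), the nuclear respiratory chain (0.0895), interferon (0.15), fatty acid oxidation (0.232), citric acid cycle (0.322), mitochondrial ribosome (0.235) and macrophage (0.232). The ranges given for lists are those of camera with the preset correlation. Ndufa12 has 1 named pseudogene. Library totals moved the median gene by 0.143 here and raised the share of higher genes among those called from 46.2% to 65.9%, and no list called here changed direction under any scaling.

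**Figure D3:**
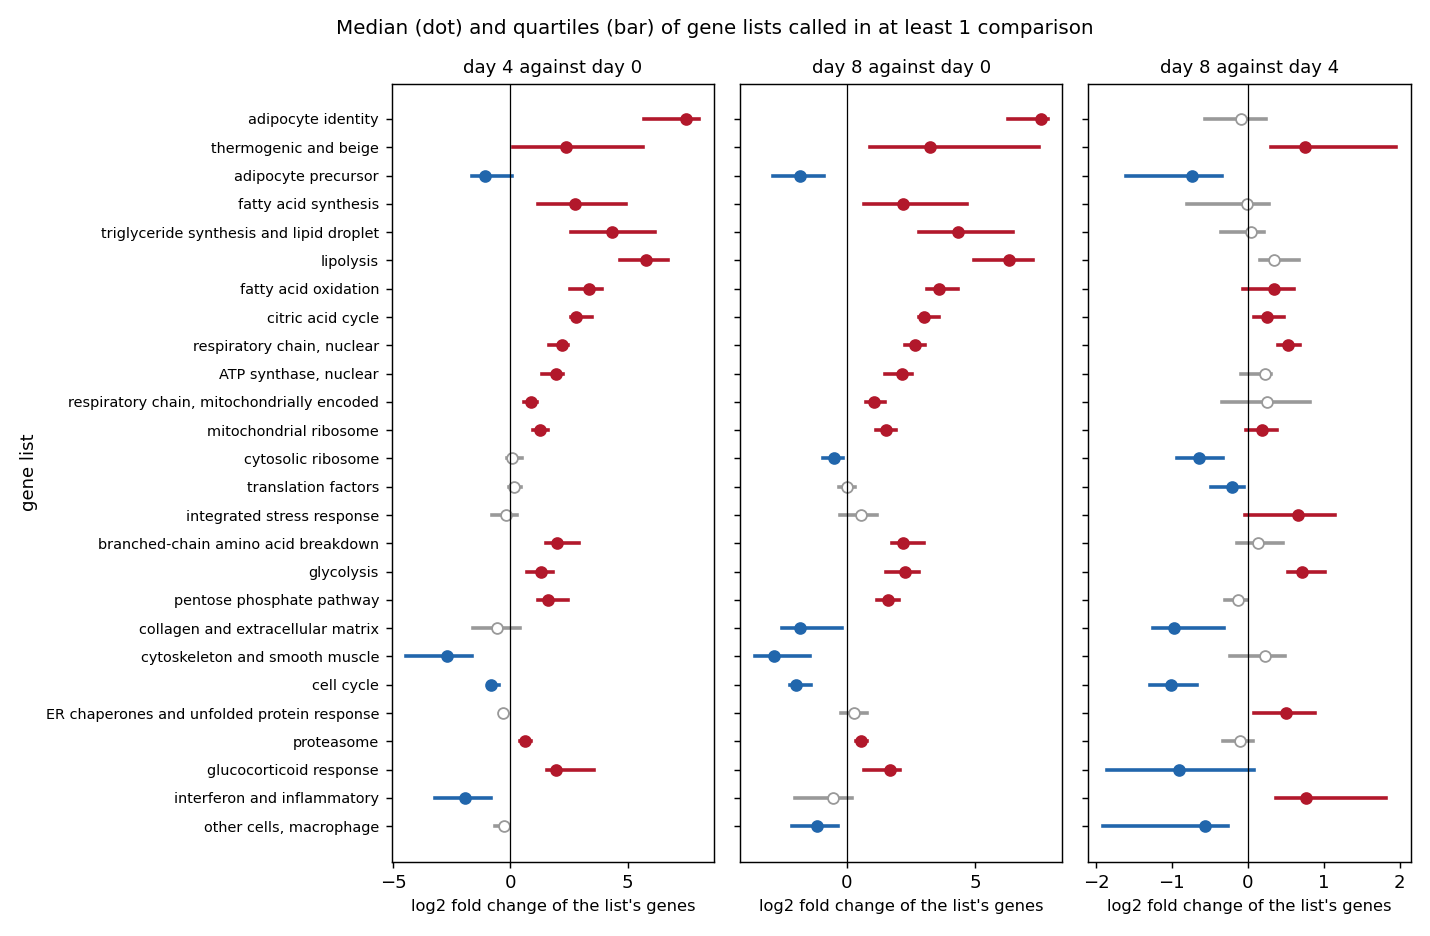
Median log2 fold change (dot) and quartiles (bar) of the genes of each list that was called in at least 1 comparison, with red for lists called higher, blue for lists called lower and open grey for lists not called. Adipocyte identity had medians of 7.50 and 7.60 against day 0 and -0.09 between days 4 and 8, where it turned positive with library totals, and the cytosolic ribosome stood at -0.64 between days 4 and 8.

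Most changes against day 0 at day 4 were also found at day 8. Of the 4387 genes higher at day 4, 3710 (84.6%) were higher at day 8, where 1501 would be shared if the calls were independent. Of the 4176 lower at day 4, 3403 (81.5%) were lower at day 8, against 1399. Both comparisons use the same day 0 libraries, so part of the 7113 shared calls above the 2900 of independent calls may come from those libraries. In 20 simulations of unchanged groups against these day 0 libraries, 0 genes were shared. No gene was changed in them, so they cannot show how much the shared libraries add when most genes change. Shared calls numbered 8313 without day 4 replicate 2 and day 8 replicate 3. Of the genes that rose by day 4, 702 rose again by day 8, 843 fell back and 2842 had no call between the days. Of those that fell, 735 fell again, 593 rose and 2848 had no call. Both calls behind these classes use the same day 4 libraries, with opposite sign. Error in those libraries therefore favours a fall after a rise and a rise after a fall, by an amount that was not tested. In 147 genes the calls against day 0 were opposite at both days, 86 of them higher at day 4 and 61 lower. These classes and the 147 genes are given with all libraries only. The classes rest on the calls between days 4 and 8, which fell from 4676 to 2706 without day 8 replicate 1. With library totals those calls were 3273 higher and 1695 lower, against 2159 and 2517.

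The makeup of the libraries shifted with the days. Mitochondrially encoded genes, ribosomal RNA genes included, held 0.625 ± 0.0425% of counts at day 0, 1.303 ± 0.141% at day 4 and 1.68 ± 0.0535% at day 8 (SD, n = 3; exact permutation p = 0.00357, the smallest possible, adjusted p = 0.00446). Its protein genes alone held 0.102 ± 0.0149%, 0.157 ± 0.0124% and 0.235 ± 0.0257%, with the same exact p. The 10 most counted genes of each library held 21.7 ± 1.11%, 14.7 ± 0.0537% and 12.5 ± 0.497%, and genes not known as protein-coding held 1.12 ± 0.0872%, 1.71 ± 0.057% and 2.31 ± 0.169%, again with the same exact p. That last share includes genes with no match in the reference table. It also includes the mitochondrial ribosomal RNA genes, so its rise overlaps with that of mitochondrially encoded genes. Cytosolic ribosomal protein genes held 0.335 ± 0.035%, 0.295 ± 0.0567% and 0.222 ± 0.0079% (exact permutation p = 0.0536), a share that depends on how reads that map to several places were counted.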

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

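Tests of depth, of a wrong label, of oligopyrimidine mRNAs and of endothelial cells were chosen after the result was seen. Among the genes named in the text, 9 were called in opposite directions against day 0 at day 4 and at day 8, which marks them for a closer look. Each also had a call between day 8 and day 4, the test of that difference, which was part of the choice. The matrix-associated gene Vit (log2 fold change -5.23 ± 0.56 SE), the decoy receptor Il1r2 (-5.10 ± 0.56), Clca3a1 (-4.87 ± 0.62), the ribosomal protein gene Rpl27 (-1.71 ± 0.17), the basement membrane collagen Col4a2 (-1.68 ± 0.19) and the elongation factor Eif5a (-0.81 ± 0.10) were higher at day 4 and lower at day 8 than at day 0. Ppp1r15a (2.31 ± 0.21), Herpud1 (1.68 ± 0.17) and Ern1 (1.36 ± 0.12), genes of the stress response and of protein folding, were lower at day 4 and higher at day 8. Calls against day 0 were near the threshold for Clca3a1 and Eif5a at day 8 (adjusted p = 0.0331 and 0.0471) and for Ppp1r15a at day 4 (adjusted p = 0.0302).

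Day 4 replicate 2 lay toward day 0. Its total of 38035996 counts was between the 36768535 and 38994892 of the other day 4 libraries, which argues against lower depth. Its lowest correlation with them (r = 0.9702) was above its highest with a library of another day (0.9499), which argues against a wrong label. Correlations did not follow the day in every case, since day 4 replicate 1 had r = 0.9711 with day 8 replicate 3 and 0.9702 with day 4 replicate 2. A mixture with day 0 RNA would have to lower the genes that rose and raise the genes that fell by 1 share, but the shares were 41.6% (38.3% to 45.5%) from 192 genes that rose and 7.75% (6.84% to 9.47%) from 174 that fell, a difference of 0.338 as a fraction. Fewer cells that became fat cells, with the rest still as at day 0, would also give 1 share, so the values argue against that simple form. Fewer such cells with the rest changed from day 0, or a slower course, may explain it and were not tested.

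Cytosolic ribosomal protein genes fell from day 4 to day 8. The median stayed at -0.507 or lower under all 4 scalings, so the choice among them does not account for the fall. The other scalings moved the median gene by only 0.00641 to 0.143 from the main one, so a large effect was unlikely. All are relative to the counts of each library and cannot show a change in total footprints. Summed counts of 322 rows named as ribosomal protein pseudogenes fell too, from 32.2 ± 9.49 to 23.3 ± 4.85 CPM. That change was -0.888% of the size of the fall of the list, which argues against counted reads that moved to rows so named. It cannot show reads that were left out or that lie in pseudogenes of other names. The median log2 change of 13 mRNAs outside the list that start with an oligopyrimidine tract was -0.703, with 10 lower (camera p = 5.06e-05, p = 0.249 with an estimated correlation), so a shared fall of this mRNA class may be part of it. Of these 13 genes 10 are also in the translation factor list. That list was itself called lower from day 4 to day 8 (camera adjusted p = 0.00807), so this test largely repeats that call. Whether mRNA level or ribosome load fell stays open, and the counts of the list are low, with a median of 7.88 CPM at day 0 against 139.5 CPM for eIF3 subunits. The median was 6.02 CPM for the 64 genes with a named pseudogene and 67.7 CPM for the 17 without. Reads that map to several places may have been left out, which the sources used here do not state, so these values could measure only part of the footprints of this list.

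Matrix genes went both ways from day 0 to day 4, with basement membrane members among the rises. A rise of that class could explain the split, but 14 basement membrane genes outside the list had a median log2 change of -0.667, with 4 higher and 5 lower. More endothelial cells would raise their markers, whose median was -0.943, with 1 of 10 higher, 2 lower and 7 not called (adjusted p = 0.252), and 1 higher and 7 lower with a median of -1.62 without day 4 replicate 2 and day 8 replicate 3. Plvap rose from 0.404 to 2.62 CPM and Eng, the most counted, fell from 94.5 to 28.1 CPM. The values argue against a rise of basement membrane genes as a class. The endothelial markers did not rise as a set, but most were not called with all libraries, so they decide little. The reason for the split stays open.

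Other groupings of the libraries were counted for each total. For each comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, reached the real number of genes (8563, 9961 and 4676, against 0 for the highest other split). For lists, 4, 8 and 7 of 10 splits reached the real number (20, 22 and 16 lists, against 25, 24 and 22 for the highest other). Splits that called 0 genes still called 8 to 25 lists. The number of lists that camera called with the preset correlation thus does not set the real grouping apart, and its small p-values need the same caution. For the 7113 shared calls, 1 of 100 drawn groupings, the real one, was as large. The highest other groupings, with 6330 and 6242, kept the day 0 libraries together and mixed those of days 4 and 8, and the rest gave 7 at most. Groupings that mix day 0 with later libraries widen the spread within groups, so few genes were likely to be called in them whatever the cause. These draws therefore do not exclude chance. They show that the shared calls went with the separation of day 0 from the later days.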

How the results depend on the processing

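The fit without day 4 replicate 2 and day 8 replicate 3 together was chosen after seeing the data. Of 214 gene results named in the text 194 kept their direction and their side of the threshold under up to 22 alternatives, 16 lost the call and 3 gained one under at least 1, and 1 changed direction. Counts of genes stayed within 1.5 times of 8563, 9961 and 4676 under the scalings, the low-count filters except the strictest, DESeq2 (8875, 10155 and 5453), limma-voom (8658, 10031 and 4821), a replicate block (8290, 9722 and 4079) and, for both comparisons with day 0, without any 1 library (7289 to 9609 and 9135 to 10693). A mean CPM of at least 10 gave 5689 genes at day 4 and 6425 at day 8 against day 0, since fewer genes were tested. A test against 1.5-fold gave 4903, 6488 and 1097, since it asks for larger changes. Without 1 library the comparison of day 8 with day 4 gave 2706 (day 8 replicate 1) to 4899 genes, with 2760 without day 8 replicate 2, where 1 group had fewer libraries. With an estimated correlation camera called 0, 0 and 0 lists (1, 0 and 0 at an unadjusted p under 0.05), since the estimate was 0.148 or higher in the called lists, while fry called 28, 30 and 12. Without 1 library the preset test called 20 to 22, 21 to 22 and 13 to 17 lists, and shared calls numbered 6248 to 8147. The share of ribosomal protein counts changed by -0.113 points from day 0 to day 8 (exact p = 0.0536), from -0.130 to -0.0946 without 1 library. It passed the threshold without day 4 replicate 1 (exact p = 0.0286) or 2 (exact p = 0.00714), and on the logit scale (-0.409, exact p = 0.025), and the cause was not tested. The other shares kept their direction and their side of the threshold without any 1 library. Pparg between days 4 and 8 (-0.07) was 0.0817 with library totals, 0.0622 without day 4 replicate 1, 0.04 without day 4 replicate 3 and -0.28 without day 4 replicate 2, and the cause was not tested. The replicate block assumes that equal numbers mark paired libraries, yet in 2 of 9 such pairs deviations correlated above 0.1. In simulated data 67% to 73% of genes changed 2-fold were recovered. Smaller changes were not simulated and recovery was not split by count, so small changes in genes of few counts may be missed.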

Other observations

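The genes below belong to lists fixed before the data were examined, and nothing in this part was tested beyond those lists. Genes that control translation went both ways. Mtor, the kinase that couples nutrients to translation, rose 3.88-fold by day 4 (log2 fold change 1.96 ± 0.14 SE) and 4.01-fold by day 8, each from 49.6 ± 2.58 CPM (SD, n = 3). Cpeb2, which binds polyadenylation elements in 3' untranslated regions, rose 5.28-fold by day 4 (2.40 ± 0.21) and fell 3.11-fold to day 8 (-1.64 ± 0.20), and its relative Cpeb1 rose 2.72-fold between those days (1.44 ± 0.15). Of 31 translation regulators 16, 15 and 6 were higher and 10, 9 and 6 lower in the comparisons day 4 with day 0, day 8 with day 0 and day 8 with day 4 (adjusted p = 0.319, 0.355 and 0.877). Translation factors rose in 19 of 47 genes and fell in 1 by day 4 (Eif2b1 2.18-fold higher), with a median of 0.15 that was -0.01 with library totals (adjusted p = 0.0542, range over its alternatives 0.00917 to 0.247), and 20 higher and 6 lower without day 4 replicate 2 and day 8 replicate 3. By day 8, 15 were higher and 13 lower than at day 0, with a median of 0.01 that turned negative with library totals, with the upper quartile and without day 4 replicate 2 and day 8 replicate 3, a mean of -0.01 and a test direction of down (adjusted p = 0.977). Ribosomal protein genes at day 4 had 16 higher and 3 lower of 81, with a median of 0.07 that was -0.09 with library totals and -0.06 with the upper quartile (adjusted p = 0.446, and 0.0476 without day 4 replicate 1, range 0.0476 to 0.955). The counts were 14 higher and 13 lower, with a median of -0.05, without day 4 replicate 2 and day 8 replicate 3. Genes that charge tRNAs split 6 higher and 8 lower of 20 by day 4 (Aars fell 1.74-fold), with a median of 0.08 that turned negative with library totals and the upper quartile, a mean of -0.03 and a test direction of down (adjusted p = 0.801). Between days 4 and 8, 4 rose and 4 fell (Wars 1.88-fold higher, Tars 1.42-fold lower, adjusted p = 0.852). Adjusted over the list alone the day 4 counts were 15 and 0 for factors and 7 and 0 for ribosomal proteins, 12 factors and 10 regulators were lower at day 8 than at day 0, 7 regulators were lower at day 8 than at day 4, and the others were the same.

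Stress, sterol and one-carbon genes at day 4 were mixed. Integrated stress response genes rose in 7 of 28 and fell in 12, with the lipoprotein receptor Vldlr 4.65-fold higher and the amino acid carrier Slc7a5 2.31-fold lower (adjusted p = 0.319). By day 8, 14 were higher and 5 lower than at day 0, with Atf3 19.7-fold higher (adjusted p = 0.171, and 0.0486 without the low-count filter, range 0.0486 to 0.32). Folding genes of the endoplasmic reticulum rose in 3 of 23 and fell in 7 by day 4 (Dnajb9 3.87-fold higher, Herpud1 1.87-fold and Ern1 1.68-fold lower, adjusted p = 0.0775, range 0.0281 to 0.116), and 11 were higher and 5 lower at day 8 than at day 0 (adjusted p = 0.204). Cholesterol synthesis rose in 10 of 24 and fell in 3 by day 4 (the sterol sensor partner Insig1 8.29-fold, Dhcr7 6.53-fold higher, adjusted p = 0.111, and 0.0482 without day 0 replicate 1, range 0.0325 to 0.488). Serine and one-carbon genes rose in 11 of 22 and fell in 4 (Cbs 9.81-fold, the serine carrier Sfxn1 6.11-fold higher, adjusted p = 0.0876, and 0.0282 without the low-count filter, range 0.0282 to 0.242). By day 4, 5 folding genes were higher and 16 lower (adjusted p = 0.0335), and 10 cholesterol genes higher and 9 lower, without day 4 replicate 2 and day 8 replicate 3. The counts were the same adjusted over the list alone.

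Markers of other cells were read at day 8 against day 0. Endothelial markers had 2 of 10 higher and 5 lower (Plvap 10.6-fold higher, Eng 5.35-fold lower, adjusted p = 0.315), mural markers 3 of 9 higher and 3 lower (Cspg4 4-fold higher, Mylk 6.29-fold lower, adjusted p = 0.418) and Schwann markers 2 of 6 higher (Erbb3 9.14-fold, adjusted p = 0.339). Of 9 lymphocyte markers 1 was higher (Ighm 2.45-fold), with a median of -0.16, a mean of 0.01 and a test direction of down (adjusted p = 0.717), and of 3 skeletal muscle markers 2 were lower (Acta1 7.07-fold, adjusted p = 0.277). The same counts came out adjusted over the list alone. Epithelial and mesothelial lists had 2 tested genes each (Krt18 and Krt19, Msln and Krt19) and the red blood cell list 0, too few for the list test.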
